A study of Mus musculus with 15 samples.

How the data were processed

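RNA was measured in 15 libraries, 3 in each of 5 groups, from 100 sorted cells per library. B cells from mice with the B1-8hi knock-in, whose antigen receptor binds the hapten NP, were transferred to C57BL6 mice, which were immunized with NP-CGG in complete Freund's adjuvant, and cells from draining lymph nodes were sorted on day 12. Dark zone cells (DZ, CXCR4-high CD86-low) and 3 light zone fractions came from donors with a Bcl6-YFP reporter. Fraction 1 was Bcl6-low CD69-high, Fraction 2 Bcl6-high CD69-high and Fraction 3 Bcl6-high CD69-low. Germinal centre derived plasmablasts (GC-PB, CD138-high CD44-high tdTomato-positive) came from donors with a tamoxifen-inducible Cre under S1pr2 and a tdTomato reporter, treated with tamoxifen on days 6, 7 and 8. Groups and replicate numbers were taken from the sample titles. The replicates are independent library preparations, and the labels do not say whether they came from separate animals. The p-values therefore measure the spread between these libraries, which may be technical.

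Per the labels, the authors added the same amount of ERCC spike-in RNA to every tube, tagged cDNA with molecular barcodes during reverse transcription, amplified it by template switching and PCR, and aligned reads to mm10 with TopHat2 (version not given). The deposited table holds a signal for 23420 genes in each library. It states no unit or scaling beyond that signal. In each library the most frequent value above 0 was taken as its constant. The values are read here as molecule counts multiplied by this constant, which the labels do not state. Between 91.0% and 92.5% of the values above 0 were whole multiples of this constant within a tolerance of 0.02 of it, and all values under 50 multiples were multiples of a hundredth of it within a tolerance of 0.02 of that hundredth. The constant ran from 0.105 to 0.362 and the total per library from 27942 to 115088. Divided by the constant, the totals stand for 184103 to 376992 molecules, and 9185 to 10132 genes were above 0 per library. The table holds no row for ERCC spike-ins, mitochondrial transcripts or immunoglobulin segments, so that mRNA content relative to the spike-in was not analysed here and the library total is reported in its place. It holds 1 immunoglobulin-related row, Igj, which took 4.23% of the total in GC-PB. Rn45s, a ribosomal RNA precursor, took 3.31% to 9.97%.

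Since the deposited values are not whole counts, limma 3.58.1 in R 4.3.3 with an intensity trend was fitted to log2(value + 1) of the 11190 genes above 0 in at least 3 libraries, with 5 group means in 1 fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes. The comparisons were Fraction 1 vs Fraction 2, Fraction 2 vs Fraction 3, the equal-weight mean of the light zone fractions vs DZ, and GC-PB vs Fraction 1. The test, the gene lists, the naming rule and the alternatives at the end of this section, apart from those given there as added, were fixed before the data were examined, with the deposited scale as the scale of the test. A scale with equal library totals (Rn45s left out of the total) and a scale by median ratios were added after the deposited totals were seen, and levels in the text are at equal totals.

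Genes named in the text are the 6 higher and the 6 lower genes with the largest change on the deposited scale among those called, with no overlap between the libraries compared and a mean in the higher group of at least 1.33, the median over tested genes. They also include up to 3 called members with the smallest p from each gene list, and sort markers and key regulators. Only 2 genes met the first part on the lower side in Fraction 2 vs Fraction 3. Genes outside this rule are marked in the text, and 2 genes that met it are not reported. With the equal totals and the median ratios, 48 of 50, 36 of 37, 56 of 56 and 49 of 51 named genes had the same sign in the 4 comparisons, in the order above. With the deposited scale and equal totals these numbers were 32, 30, 53 and 49. Positions came from the GENCODE annotation of the mouse, which placed 163 of the 165 named genes.

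For 29 gene lists, 23 of them with at least 5 tested members, camera tested whether a list moved relative to all other genes, with a preset correlation of 0.01 and with a correlation estimated from the residuals. Its p was adjusted over 92 tests (23 lists in 4 comparisons) on each scale. Of these, 49 were called on the deposited scale, 16 of them with an estimated correlation, and 49 at equal totals, 32 of them with an estimated correlation. The set test fry, fixed beforehand, asks whether a list moved on its own and not against other genes. Its p is given in the text for 1 comparison only. Members were also counted after adjustment over the list alone. Library totals were compared by exact permutation tests, two-sided. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

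The method was tested on simulated data with 200 genes changed by 2 or 4 fold. On the equal total scale it recovered 26.8% to 32.0% of the changes of 2 fold and 51.0% to 62.9% of those of 4 fold, and among genes above the naming minimum 95.4%, 97.7%, 100% and 93.6% of those of 4 fold in the 4 comparisons. At most 5.1% of the calls were false on this scale and 8.54% on the deposited scale. All simulated groups shared the same profile apart from the changed genes, and the same dispersion (0.00407). The real GC-PB replicates varied more than those of the other groups. Recovery and false shares may therefore be too favourable for GC-PB vs Fraction 1. The libraries simulated for the deposited scale were given about the same total, unlike the real ones. The 8.54% therefore does not cover deposited calls that follow the library totals. Among genes above the naming minimum, 57.45%, 61.36%, 56.6% and 64.86% of the changes of 2 fold were recovered at equal totals in the 4 comparisons. Many changes of 2 fold, above all in low genes, could therefore be missed with 3 libraries per group. Replicates had Pearson correlations across genes of 0.931 to 0.974, which describe genes and not independent replicates. Over genes with at least 20 molecules, the variance between replicates was 1.08 to 1.29 times that of counting in 4 groups and 1.64 to 3.90 times in GC-PB. Correlations of residuals between libraries with the same replicate number ran from -0.063 to 0.052, so that no pairing was used. With a spread this near to that of counting in 4 groups, a weak pairing could be missed.

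The alternatives were other pseudocounts (0.1 and 10), no filter and a stricter filter on low values, the groups compared alone, the replicate number as a block, a test against a fold change of 1.5, other reference groups, other programme sizes, and each library left out in turn. Added after the data were seen were the other scales, library weights, Fractions 2 and 3 alone against DZ, and programmes defined by GC-PB against Fraction 1 or without GC-PB replicate 1. Scaling to spike-in rows was foreseen but had no rows to use. Tests for whole counts were foreseen and not run, since the deposited values are not whole counts and not all of them are after division by the constant.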

Results

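Changes are log2 fold changes ± SE at equal library totals, with adjusted p from limma, and the change on the deposited scale follows them. Levels are values at equal library totals, as mean ± SD over n = 3 libraries per group, and positions are on mm10.

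The deposited library totals differed between the groups. The mean total was 110747 ± 3890 (SD, n = 3) in Fraction 1, 72158 ± 5981 in GC-PB, 40216 ± 1843 in Fraction 2, 32750 ± 2668 in DZ and 30564 ± 2305 in Fraction 3. The ratio of mean totals was 2.75 for Fraction 1 to Fraction 2, 1.32 for Fraction 2 to Fraction 3 and 0.652 for GC-PB to Fraction 1, each with an exact permutation p of 0.1. This is the smallest p that 3 libraries against 3 can give. It was 0.933 for Fraction 3 to DZ (exact permutation p = 0.5). Each total was divided by the constant of its library to give the number of molecules behind it. This number was 348639 ± 25932 in Fraction 1 and 350126 ± 16840 in Fraction 2, a ratio of 0.996. For the other pairs the ratio of molecules was 1.40 (Fraction 2 to Fraction 3), 0.882 (Fraction 3 to DZ) and 0.578 (GC-PB to Fraction 1). That constant was 0.305 to 0.362 in the Fraction 1 and GC-PB libraries and 0.105 to 0.139 in the DZ, Fraction 2 and Fraction 3 libraries. As deposited, the median of all tested genes moved by 0.64 from Fraction 2 to Fraction 1 and by 0.15 from Fraction 3 to Fraction 2. It moved by 0.28 from DZ to the light zone fractions and by -0.42 from Fraction 1 to GC-PB. At equal totals these medians were -0.04, 0.00, 0.00 and -0.06.

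The same 6 libraries that had the larger constant also carried Xist (chromosome X, 103460366 to 103483254), the transcript of the inactive X chromosome. Xist was 10.5 ± 1.56 in Fraction 1 and 12.8 ± 1.71 in GC-PB and was listed at 0 in the 9 other libraries. Ddx3y (chromosome Y, 1260771 to 1286629) was 4.8 ± 0.774 in Fraction 2, 5.47 ± 0.585 in Fraction 3 and 5.19 ± 1.17 in DZ, against 0.0254 in Fraction 1 and 0 in GC-PB. Fraction 2 vs Fraction 3 and GC-PB vs Fraction 1 lie on 1 side of this divide each. Fraction 1 vs Fraction 2 crosses it with all of its libraries, so that the divide and the cell fraction cannot be told apart there. The light zone comparison is also given for Fractions 2 and 3 alone.

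**Figure D1:**
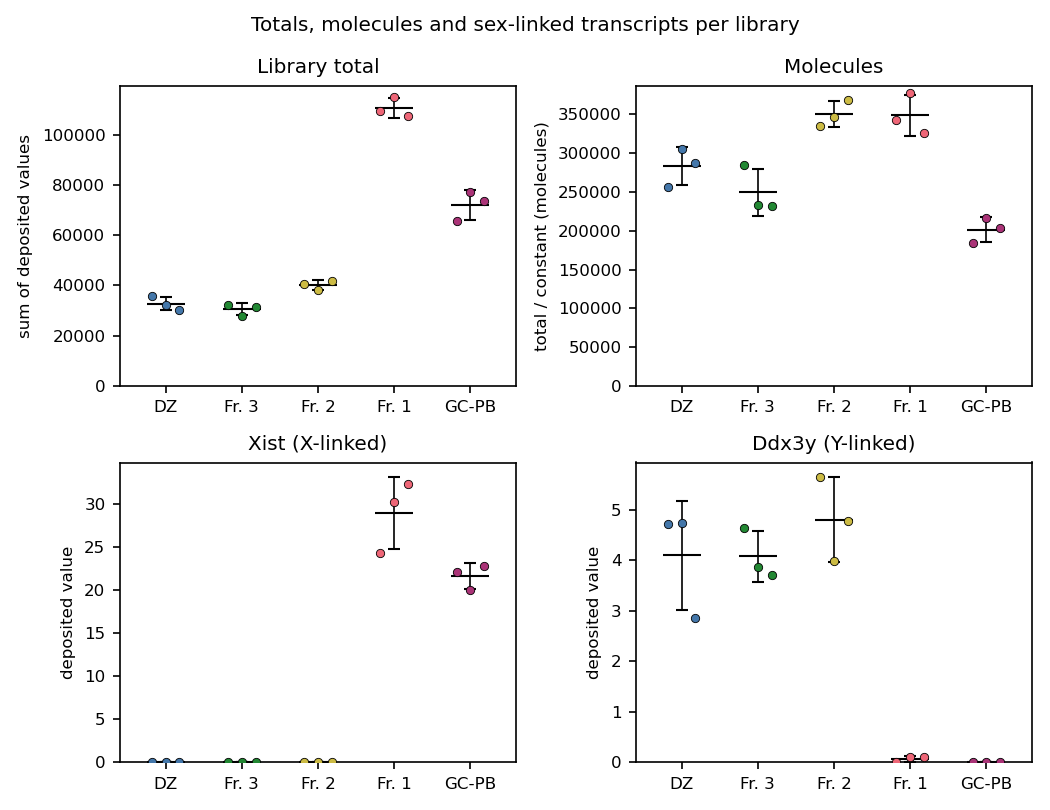
Library total, molecules behind it, Xist and Ddx3y in each of the 15 libraries, in deposited signal units except for the molecules. Points are libraries, and bars are the mean ± SD of 3 libraries per group. Mean totals run from 30564 in Fraction 3 to 110747 in Fraction 1, while mean molecules are 350126 in Fraction 2 and 348639 in Fraction 1.

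Bcl6-low CD69-high light zone cells (Fraction 1) held more transcript of Ccnd2, Batf, Myc and Irf4 than Bcl6-high CD69-high light zone cells (Fraction 2), and at equal totals less of the germinal centre genes Bcl6, Mybl1, S1pr2 and Bach2. Ccnd2 (cyclin D2, chromosome 6, 127125162 to 127152193), which drives entry into the cell cycle, was 30.7 ± 4.57 against 5.38 ± 2.2, a change of 2.35 ± 0.22 (adjusted p = 1.09e-06, deposited 3.78). Batf (chromosome 12, 85686669 to 85709087), a transcription factor of activated lymphocytes, was 20.9 ± 3.57 against 4.39 ± 0.84 (2.02 ± 0.20, adjusted p = 1.38e-06, deposited 3.44). Myc was 12.2 ± 2.24 against 4.46 ± 0.641 (1.27 ± 0.23, adjusted p = 0.00107, deposited 2.65). Irf4, which acts in a dose-dependent way in plasma cell formation, was 5.44 ± 0.944 against 1.6 ± 0.572 (1.33 ± 0.21, adjusted p = 0.000403, deposited 2.63).

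Bcl6 (chromosome 16, 23965052 to 23988852) is the repressor that maintains the germinal centre state, and its reporter was used in the sort. It was 3.97 ± 1.03 in Fraction 1 against 15.5 ± 2.03 in Fraction 2 (-1.75 ± 0.16, adjusted p = 5.45e-07, deposited -0.49, adjusted p = 0.0268). The call as deposited was lost without Fraction 2 replicate 1 (-0.51), Fraction 2 replicate 2 (-0.43) or Fraction 1 replicate 1 (-0.28). Mybl1 was 0.5 ± 0.0341 against 6.54 ± 0.352 (-2.33 ± 0.16, adjusted p = 8.71e-09, deposited -1.67). S1pr2, the receptor that holds cells in the germinal centre, was 2.87 ± 1.27 against 10.9 ± 0.824 (-1.67 ± 0.19, adjusted p = 8.32e-06, deposited -0.50 with adjusted p = 0.0732). Bach2, a repressor of plasma cell differentiation, fell at equal totals from 11.7 ± 0.942 to 5.9 ± 0.415 (-0.88 ± 0.12, adjusted p = 0.000104), but its change on the deposited scale was 0.43. The call of that deposited rise was lost without Fraction 2 replicate 2 (0.35) or Fraction 1 replicate 1 (0.39) or 2 (0.42). Mef2b fell at equal totals (-1.35) without passing as deposited (adjusted p = 0.999). Foxo1 (-0.85) and Cxcr4 (-0.84) fell at equal totals with deposited changes of 0.40 and 0.21. Ptprc, which encodes CD45 and its B220 form, fell by 1.13 at equal totals against a deposited change of 0.26. Spib was 10.4 against 15.4 (-0.51, deposited 0.87). Its call at equal totals was lost without Fraction 2 replicate 2 (-0.42) or 3 (-0.49), or Fraction 1 replicate 1 (-0.51), 2 (-0.46) or 3 (-0.55).

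At equal totals, plasma cell genes did not move together between these fractions. Prdm1 (chromosome 10, 44437177 to 44528501), which encodes the plasma cell regulator Blimp-1, was 0.0392 in Fraction 1 and 0.0401 in Fraction 2 (adjusted p = 1). Prdm1 was near the lower limit of the values in both fractions, so that only a large difference could have been seen. Xbp1 was 4.5 ± 1.35 against 5.56 ± 1.55 (-0.26 ± 0.19, adjusted p = 0.5, deposited 1.01). In the plasma cell programme 3 of 25 tested members rose and 4 fell, 3 and 6 adjusted over the list alone. The camera adjusted p was 0.784, and 0.842 with an estimated correlation. As deposited, 13 members were higher and 0 lower (camera adjusted p = 0.735, and adjusted p = 0.8125 with an estimated correlation).

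Of the genes ranked on the deposited scale and without overlap between libraries, others high in the ranking for Fraction 1 were Fscn1, which encodes the actin bundling protein fascin (2.12 ± 0.18, deposited 3.52), and Rilpl2 (2.15 ± 0.24, deposited 3.48). Cidec, a lipid droplet gene on chromosome 6, was 7.24 ± 1.82 in Fraction 1 and 15.6 ± 3.04 in GC-PB and listed at 0 in the 9 other libraries. It follows the same divide as Xist, so that its difference here cannot be assigned to Fraction 1. In the same ranking, the lower genes besides the Y-linked Ddx3y and Eif2s3y included Nuggc (-1.75 ± 0.18, deposited -1.09), Efnb1 (-1.60 ± 0.22, deposited -1.07) and Mxd3 (-1.18 ± 0.28, deposited -1.11). Cd44, an adhesion receptor, rose to 10.3 ± 0.86 from 2.97 ± 1 (1.54 ± 0.19, deposited 2.92). Cd86 was 7.24 against 4.89 (0.50, adjusted p = 0.188, deposited 1.84). Cd69, the marker that both fractions share, was 2.65 ± 0.871 against 2.91 ± 0.884 (-0.11, adjusted p = 0.926, deposited 1.06). Irf8 (-0.49, adjusted p = 0.165), Ebf1 (0.17, adjusted p = 0.769) and Pax5 (0.0717 against 0.153) did not pass over all genes at equal totals. Sdc1 was 0.0392 in Fraction 1 and listed at 0 in Fraction 2. Pax5 and Sdc1 were near the lower limit of the values, so that only large differences could have been seen.

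Growth and activation genes rose together in Fraction 1. Among MYC targets and genes of ribosome biogenesis, 32 of 40 tested members rose, 37 adjusted over the list alone (camera adjusted p = 0.00105 with an estimated correlation). Pa2g4 changed by 0.89, Eif4a1 by 0.77 and Odc1 by 0.62. In NF-kB and CD40 targets 11 of 29 tested members rose and 0 fell, 17 and 1 adjusted over the list alone (camera adjusted p = 0.00525 with an estimated correlation). The survival genes Bcl2a1d (1.64), Bcl2a1b (1.52) and Birc3 (0.80) were among them. Of the light zone activation genes, 12 of 29 tested members rose and 1 fell, 21 and 2 adjusted over the list alone (camera adjusted p = 0.0177 with an estimated correlation). In glycolysis 4 of 20 tested members rose, 4 adjusted over the list alone (camera adjusted p = 0.0307 with an estimated correlation). Hk2 changed by 1.11 and Ldha by 0.61. On the deposited scale 40 of the 40 MYC targets and 17 of the 20 glycolysis genes were higher. Relative to all genes these lists then had camera adjusted p = 3.5e-19 and 0.00033 with the preset correlation. With an estimated correlation they had adjusted p = 0.0581 and adjusted p = 0.0999. In T cell help and adhesion 3 of 21 tested members rose and 0 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 0.00558, and adjusted p = 0.0528 with an estimated correlation).

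Germinal centre, dark zone and mitosis genes fell together at equal totals. On the deposited scale only the mitosis list of these lay lower relative to all genes by camera, and only with the preset correlation. In germinal centre and B cell identity 20 of 29 tested members fell, 21 adjusted over the list alone (camera adjusted p = 0.00041 with an estimated correlation). As deposited, 18 members were higher and 1 lower (adjusted p = 0.636 with an estimated correlation). Among dark zone genes outside the cell cycle 0 of 18 tested members rose and 10 fell, 1 and 12 adjusted over the list alone (camera adjusted p = 0.00105 with an estimated correlation). As deposited, 8 of them were higher (adjusted p = 0.555 with an estimated correlation). In G2/M and mitosis 23 of 35 tested members fell, 32 adjusted over the list alone (camera adjusted p = 0.0219 with an estimated correlation). As deposited, 9 mitosis genes were higher and 1 lower. Relative to all genes the list was then lower with the preset correlation (camera adjusted p = 0.000168, and adjusted p = 0.475 with an estimated correlation). The mitosis genes Mki67 (-1.60, deposited -0.23), Top2a (-1.20, deposited 0.19) and Cenpe (-1.56, deposited -0.39) were chosen after their values were seen. In G1/S and DNA replication 8 of 32 tested members fell, 10 adjusted over the list alone. The call of this list was lost with an estimated correlation (camera adjusted p = 9.24e-08, and adjusted p = 0.158 with an estimated correlation).

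For MHC class II genes the direction depended on the scale. At equal totals 1 of 15 tested members rose and 5 fell, 1 and 7 adjusted over the list alone (camera adjusted p = 0.000805, and adjusted p = 0.113 with an estimated correlation). As deposited, 13 members were higher (adjusted p = 0.0184, and adjusted p = 0.224 with an estimated correlation). Other lists passed no camera test at equal totals. By fry, which tests a list on its own and not against other genes, 5 of them passed there. These were apoptosis regulators (adjusted p = 0.00261), migration and positioning (0.00968), class switching and somatic hypermutation (0.000931), sort markers (0.000521) and key regulators (0.0458). The unfolded protein response list had 2 higher and 3 lower of 37 tested genes, 2 and 3 adjusted over the list alone. It just missed with the preset correlation (camera adjusted p = 0.0554). It passed without Fraction 2 replicate 1 (0.17 above the mean of all genes) or Fraction 1 replicate 1 (0.14). Immediate early genes of the antigen receptor had 2 higher and 2 lower of 24 tested genes, 5 and 4 adjusted over the list alone. Oxidative phosphorylation had 2 higher and 0 lower of 48 tested genes, 2 and 0 adjusted over the list alone, and apoptosis regulators had 4 higher and 1 lower of 23 tested genes, 6 and 1 adjusted over the list alone. As deposited, 34 genes of the unfolded protein response and 48 of oxidative phosphorylation were higher. Relative to all genes both lists then passed with the preset correlation (camera adjusted p = 1.7e-07 and 3.3e-15) but not with an estimated correlation (adjusted p = 0.103 and adjusted p = 0.156). Migration and positioning had 2 higher and 2 lower of 19 tested genes, 2 and 4 adjusted over the list alone, and memory B cell markers had 2 higher and 1 lower of 18 tested genes, 3 and 1 adjusted over the list alone. Class switching and somatic hypermutation had 1 higher and 3 lower of 20 tested genes, 1 and 3 adjusted over the list alone. Naive follicular B cell markers had 2 higher and 1 lower of 10 tested genes, 2 and 1 adjusted over the list alone. In cholesterol synthesis and in the interferon response no member passed at equal totals by limma.

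Over all 11190 tested genes, limma called 424 higher and 587 lower in Fraction 1 at equal totals, and 6120 higher and 63 lower as deposited. Of the genes called higher as deposited, 144 were called lower at equal totals. The count at equal totals, 1011, was 551 without Fraction 2 replicate 2, 631 without Fraction 2 replicate 3, 578 without Fraction 1 replicate 1, 667 without Fraction 1 replicate 2 and 656 without Fraction 1 replicate 3.

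**Figure D2:**
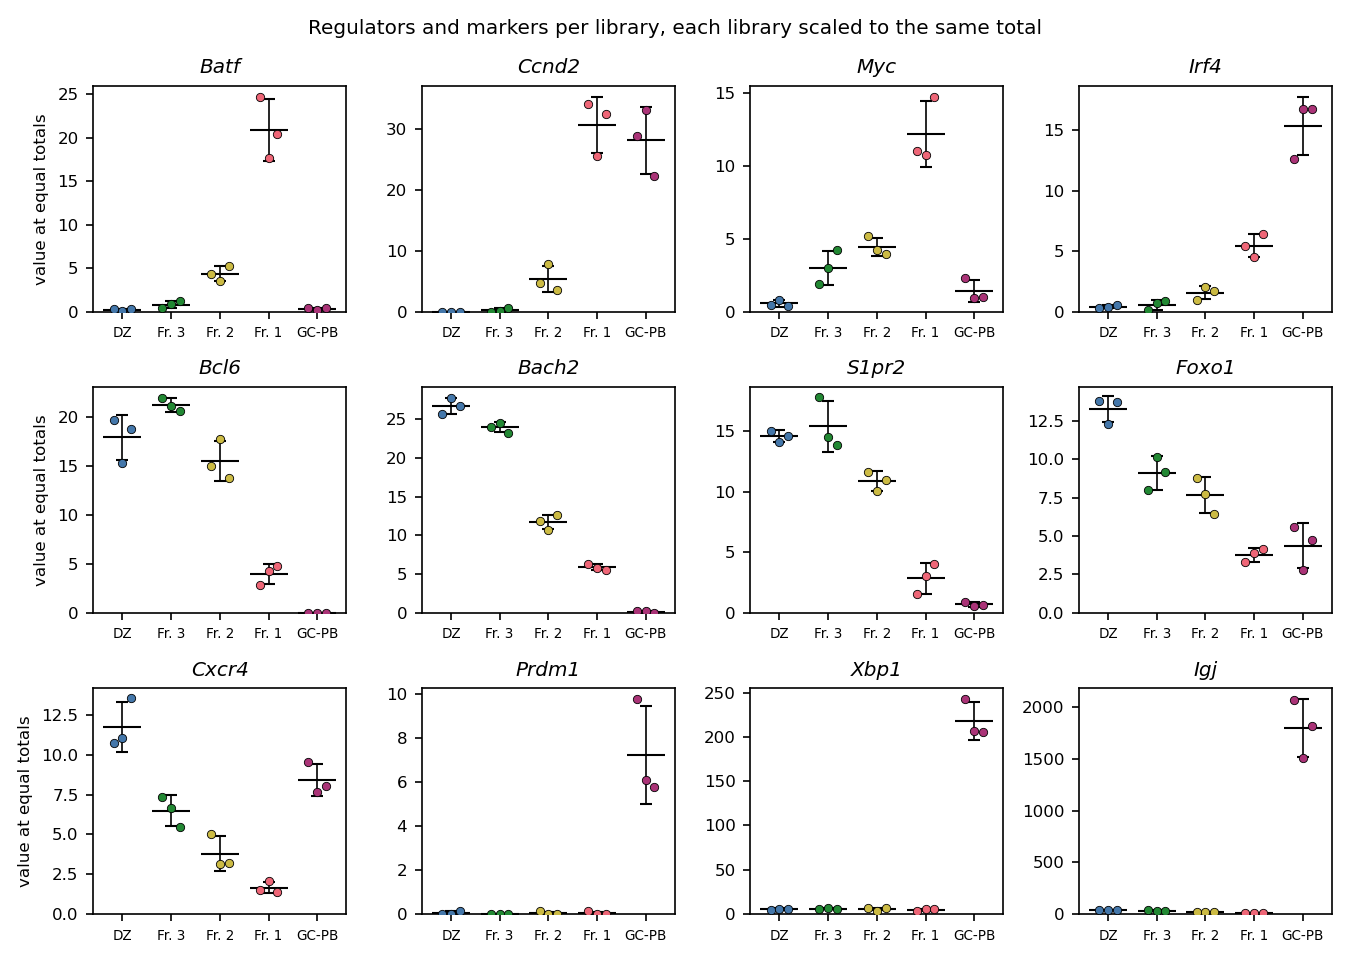
Values at equal library totals (signal units) of Batf, Ccnd2, Myc, Irf4, Bcl6, Bach2, S1pr2, Foxo1, Cxcr4, Prdm1, Xbp1 and Igj in the 5 groups. Points are libraries and bars are the mean ± SD of 3 libraries. Batf runs from 0.249 in DZ to 20.9 in Fraction 1, and Bach2 from 26.7 in DZ to 0.143 in GC-PB. As deposited Bach2 is higher in Fraction 1 than in Fraction 2, with a call that depends on single libraries.

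Within the Bcl6-high light zone cells, the CD69-high cells (Fraction 2) held more Ccnd2 and Batf than the CD69-low cells (Fraction 3) and, at equal totals, less Bach2. Ccnd2 was 5.38 ± 2.2 against 0.293 ± 0.367 (2.29 ± 0.22, adjusted p = 1.82e-05, deposited 2.35). Batf was 4.39 ± 0.84 against 0.848 ± 0.4 (1.56 ± 0.20, adjusted p = 0.000442, deposited 1.73). Ddt and Mif, neighbouring and related genes on chromosome 10, were 11.7 ± 1.56 against 3.91 ± 0.997 (1.38 ± 0.18, deposited 1.70) for Ddt and 43 ± 4.93 against 18.7 ± 3.79 (1.18 ± 0.17, deposited 1.57) for Mif. Bach2 was 11.7 ± 0.942 against 23.9 ± 0.647 (-0.97 ± 0.12, adjusted p = 0.000442, deposited -0.57 with adjusted p = 0.0529). Arid5a (1.52 ± 0.24, deposited 1.59) and Bcl2a1b (1.12 ± 0.19, deposited 1.39) were higher in Fraction 2. Pxdc1 (-1.30 ± 0.20, deposited -0.97) and Cyp4f18 (-1.13 ± 0.20, deposited -0.83) were lower, but as deposited their calls depended on single libraries. Cyp4f18 lost it without any 1 of the 6 libraries (-0.905 to -0.765), and Pxdc1 without any 1 other than Fraction 3 replicate 1 (-0.999 to -0.871). At equal totals Cyp4f18 lost its call without Fraction 3 replicate 2 (-1.01) or Fraction 2 replicate 1 (-1.09).

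MYC targets rose in Fraction 2, while Myc itself was 4.46 ± 0.641 against 3.03 ± 1.17 and did not pass over all genes (0.47 ± 0.23, adjusted p = 0.441, deposited 0.77). In the list 10 of 40 tested members rose, 32 adjusted over the list alone (camera adjusted p = 0.00105 with an estimated correlation). Ncl, which encodes nucleolin, was 44.3 against 23.9 (0.88). Of the NF-kB and CD40 targets 5 of 29 tested members rose, 5 adjusted over the list alone (camera adjusted p = 0.0253 with an estimated correlation). Birc3 changed by 0.97 and Bcl2a1d by 1.13, where Bcl2a1d was not called without Fraction 2 replicate 2 (0.97). In light zone activation 7 of 29 tested members rose and 0 fell, 8 and 1 adjusted over the list alone. The call was lost with an estimated correlation at equal totals (camera adjusted p = 4.38e-07, and adjusted p = 0.0856 with an estimated correlation) but not as deposited (adjusted p = 0.0262). Glycolysis rose as a list at equal totals (camera adjusted p = 0.0224 with an estimated correlation, and adjusted p = 0.0732 as deposited), with 3 members that passed adjusted over the list alone.

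Germinal centre identity, dark zone and migration genes fell as lists at equal totals. In germinal centre and B cell identity 2 of 29 tested members fell, 9 adjusted over the list alone (camera adjusted p = 0.0014 with an estimated correlation). Among dark zone genes outside the cell cycle 1 of 18 tested members fell, 5 adjusted over the list alone (camera adjusted p = 0.00156 with an estimated correlation). As deposited these lists had camera adjusted p = 0.0236 and 0.0129 with the preset correlation. With an estimated correlation they had adjusted p = 0.183 and adjusted p = 0.162. Migration and positioning had no member that passed by limma, and as a list it had camera adjusted p = 0.0451 with an estimated correlation, with adjusted p = 0.0771 as deposited. The call of oxidative phosphorylation was lost with an estimated correlation (camera adjusted p = 0.000354, and adjusted p = 0.263 with an estimated correlation). So were those of MHC class II (camera adjusted p = 0.0144, and adjusted p = 0.232 with an estimated correlation) and cholesterol synthesis (camera adjusted p = 0.0265, and adjusted p = 0.0856 with an estimated correlation). The MHC class II genes were lower at equal totals and higher as deposited. Their call was lost without Fraction 3 replicate 2, with a difference of -0.12 from the mean of all genes. That of cholesterol synthesis was lost without Fraction 3 replicate 3 (-0.13) or Fraction 2 replicate 2 (-0.14). Immediate early genes (camera adjusted p = 0.0196, and adjusted p = 0.514 with an estimated correlation) lost theirs without Fraction 3 replicate 2 (-0.16) or Fraction 3 replicate 3 (-0.14).

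Of the sort markers and key regulators, Bach2 and Batf passed at equal totals between Fractions 2 and 3. Bcl6 was 15.5 ± 2.03 against 21.3 ± 0.698 (-0.44, adjusted p = 0.26). Cd69, the marker that separates these fractions, was 2.91 ± 0.884 against 2.17 ± 0.501 (0.29, adjusted p = 0.863). Irf4 was 1.6 ± 0.572 against 0.575 ± 0.384 (0.73, adjusted p = 0.142, deposited 0.86 with adjusted p = 0.0442), and its call as deposited was lost without any 1 of the 6 libraries of these fractions (0.69 to 1.05). S1pr2 (-0.46), Spib (-0.52) and Cxcr4 (-0.67) did not pass over all genes. Sort markers had 0 higher and 0 lower of 8 tested genes, 0 and 3 adjusted over the list alone (camera adjusted p = 0.044, and adjusted p = 0.123 with an estimated correlation). The call was also lost without Fraction 3 replicate 1 (-0.15 from the mean of all genes), 2 (-0.15) or 3 (-0.16) or Fraction 2 replicate 3 (-0.09). Key regulators had 1 higher and 1 lower of 14 tested genes, 2 and 3 adjusted over the list alone (camera adjusted p = 0.456, and adjusted p = 0.704 with an estimated correlation). Prdm1 was 0.0401 in Fraction 2 and listed at 0 in Fraction 3, at or near the lower limit of the values.

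Between these fractions, limma called 49 genes higher and 28 lower in Fraction 2 at equal totals, and 299 higher and 2 lower as deposited. The 77 genes at equal totals were 39 without Fraction 3 replicate 1, 25 without Fraction 3 replicate 2, and 34 without Fraction 3 replicate 3. They were 21 without Fraction 2 replicate 1, 23 without Fraction 2 replicate 2 and 17 without Fraction 2 replicate 3. The 301 as deposited were 201 without Fraction 3 replicate 1, 42 without Fraction 3 replicate 2, and 105 without Fraction 3 replicate 3. They were 61 without Fraction 2 replicate 1, 122 without Fraction 2 replicate 2 and 54 without Fraction 2 replicate 3.

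The light zone fractions as a mean held more Batf, Myc, Nfkbia, Cd83 and Bcl2a1b than the dark zone cells (CXCR4-high CD86-low) and less Pafah1b3, Myl4, Vim and Cxcr4. Batf was 0.249 ± 0.0975 in DZ, 0.848 ± 0.4 in Fraction 3, 4.39 ± 0.84 in Fraction 2 and 20.9 ± 3.57 in Fraction 1 (2.26 ± 0.16, adjusted p = 1.5e-08, deposited 2.73). In Fractions 2 and 3 alone the change was 1.32 (adjusted p = 8.97e-05). Myc was 0.581 ± 0.215 in DZ against 3.03, 4.46 and 12.2 in Fractions 3, 2 and 1 (2.05 ± 0.19, deposited 2.53, Fractions 2 and 3 alone 1.55). Nfkbia, the NF-kB inhibitor that NF-kB induces, rose from 3.25 ± 0.921 in DZ (1.96 ± 0.25, deposited 2.57, Fractions 2 and 3 alone 1.56). Cd83 rose as well (1.92 ± 0.19, deposited 2.52, Fractions 2 and 3 alone 1.77). Fscn1 (1.97 ± 0.15, Fractions 2 and 3 alone 1.07) and Bcl2a1b (1.87 ± 0.15, Fractions 2 and 3 alone 1.17) were also high in the ranking on the deposited scale among genes without overlap.

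The gates were seen in their own transcripts. Cxcr4 was 11.8 ± 1.57 in DZ against 6.5, 3.78 and 1.64 in Fractions 3, 2 and 1 (-1.49 ± 0.14, adjusted p = 5.25e-07, deposited -0.95). Cd86 was 1.59 ± 1.05 against 5.16, 4.89 and 7.24 (1.44 ± 0.18, adjusted p = 1.57e-05, deposited 1.96). In Fractions 2 and 3 alone these changes were -1.10 and 1.28. Pafah1b3 was 12.6 ± 1.78 in DZ and 3.74 ± 1.23 in Fraction 3 (-2.22 ± 0.20, deposited -1.76, Fractions 2 and 3 alone -1.85). Other lower genes in this ranking on the deposited scale were Myl4 (-1.84, Fractions 2 and 3 alone -1.81), Vim, an intermediate filament gene (-1.64, -1.08), Rgcc (-1.51, -1.30), Trp53inp1 (-1.41, -0.97) and Serinc5 (-1.34, -1.13).

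Among key regulators, Bach2 (-1.09, deposited -0.46, Fractions 2 and 3 alone -0.64) and Foxo1, which maintains the dark zone (-0.94, -0.33, -0.62), were lower in the light zone. Bcl6 was lower over the 3 fractions (-0.63, deposited -0.02), as were S1pr2 (-0.80, deposited -0.22) and Spib (-0.70, deposited -0.04). In Fractions 2 and 3 alone they were 0.02, -0.16 and -0.44, in the same order, and did not pass over all genes. Irf4 rose over the 3 fractions (1.03, deposited 1.52), with 0.47 in Fractions 2 and 3 alone (adjusted p = 0.255).

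Genes of activation, antigen presentation, glycolysis and cholesterol synthesis were higher in the light zone, while those of oxidative phosphorylation did not move as a list at equal totals. In light zone activation 21 of 29 tested members rose, 22 adjusted over the list alone (camera adjusted p = 0.0032 with an estimated correlation). In NF-kB and CD40 targets 19 of 29 tested members rose, 21 adjusted over the list alone (camera adjusted p = 0.00107 with an estimated correlation). Ccnd2 changed by 2.62 and Birc3 by 1.39. Of the MHC class II genes 7 of 15 tested members rose and 0 fell, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0451 with an estimated correlation). They included Ifi30, a lysosomal thiol reductase (1.39), and H2-Aa (0.60). Of the MYC targets 34 of 40 tested members rose, 39 adjusted over the list alone (camera adjusted p = 0.001 with an estimated correlation), with Nop58 at 0.98. In glycolysis 8 of 20 tested members rose, 10 adjusted over the list alone (camera adjusted p = 0.00196 with an estimated correlation), with Ldha at 0.98. In cholesterol synthesis 5 of 20 tested members rose, 12 adjusted over the list alone (camera adjusted p = 0.00252 with an estimated correlation, and adjusted p = 0.0581 as deposited), with Idi1 at 1.14. Oxidative phosphorylation had 5 higher and 3 lower of 48 tested genes, 5 and 3 adjusted over the list alone (camera adjusted p = 0.772, and adjusted p = 0.923 with an estimated correlation). As deposited 40 were higher (camera adjusted p = 5.9e-11, and adjusted p = 0.23 with an estimated correlation). Among unfolded protein response genes 10 of 37 tested members rose and 2 fell, 12 and 2 adjusted over the list alone (camera adjusted p = 0.0433 with an estimated correlation, and adjusted p = 0.0613 as deposited). Hspa5 (0.97), Calr (0.68) and P4hb (0.76), which encode ER chaperones, rose. In apoptosis regulators 4 of 23 tested members rose and 1 fell, 4 and 2 adjusted over the list alone (camera adjusted p = 0.0451 with an estimated correlation). This call was lost without DZ replicate 2 (0.22 above the mean of all genes) and as deposited (adjusted p = 0.253).

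Among dark zone genes outside the cell cycle 1 of 18 tested members rose and 13 fell, 2 and 13 adjusted over the list alone (camera adjusted p = 0.000427 with an estimated correlation). Gcsam, a germinal centre signalling adaptor, changed by -1.55. In germinal centre and B cell identity 2 of 29 tested members rose and 13 fell, 2 and 14 adjusted over the list alone (camera adjusted p = 0.00557 with an estimated correlation). This list had adjusted p = 0.475 as deposited and 0.44 in Fractions 2 and 3 alone. Mitosis had 0 higher and 10 lower of 35 tested genes, 0 and 12 adjusted over the list alone, and the call was lost with an estimated correlation (camera adjusted p = 2.11e-07, and adjusted p = 0.164 with an estimated correlation). T cell help and adhesion had 6 higher and 1 lower of 21 tested genes, 6 and 1 adjusted over the list alone, and its call was lost too (camera adjusted p = 0.0106, and adjusted p = 0.0692 with an estimated correlation). In Fractions 2 and 3 alone, with 23 set tests, light zone activation had 15 higher and 0 lower genes (adjusted p = 0.00325 with an estimated correlation), NF-kB and CD40 targets 11 higher and 0 lower genes (0.00197) and MHC class II 8 higher and 0 lower genes (0.00325). MYC targets had 7 higher and 0 lower genes (0.00325), cholesterol synthesis 2 higher and 0 lower genes (0.0016) and dark zone genes 1 higher and 7 lower genes (0.0016).

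Over all genes, limma called 459 higher and 522 lower in the light zone at equal totals and 3267 higher and 112 lower as deposited. In Fractions 2 and 3 alone it called 116 higher and 153 lower at equal totals, and 89 and 38 as deposited. The 981 genes at equal totals were 624 without DZ replicate 1, 574 without DZ replicate 2 and 642 without DZ replicate 3, and the 3379 as deposited were 2238 without DZ replicate 2 and 2125 without DZ replicate 3.

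Plasmablasts derived from germinal centre cells (GC-PB, CD138-high, fate-mapped by S1pr2) held far more of the secretory transcripts than Fraction 1 and little of the B cell and activation genes that Fraction 1 expressed. Igj, the joining chain of secreted antibody, was 1799.7 ± 282 against 6.02 ± 1.68 (8.02 ± 0.14, adjusted p = 8.61e-20, deposited 7.46). Xbp1 (chromosome 11, 5520659 to 5525893), which drives the secretory programme, was 218 ± 21.4 against 4.5 ± 1.35 (5.35 ± 0.19, deposited 4.83). Prdm1 was 7.22 ± 2.22 against 0.0392 (2.95 ± 0.18, adjusted p = 4.48e-11, deposited 3.55). Irf4 was 15.3 ± 2.4 against 5.44 ± 0.944 (1.34 ± 0.21, deposited 0.76). Batf was 0.359 against 20.9 ± 3.57 (-4.01 ± 0.20, adjusted p = 1.47e-12, deposited -5.19). Bach2 was 0.143 (-2.60 ± 0.12, deposited -3.81), and Bcl6 was listed at 0 in all 3 GC-PB libraries.

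Other genes high in the ranking on the deposited scale without overlap were, for GC-PB, Ly6c2 (174 ± 90.6 against 0.0803), Slpi, a secreted protease inhibitor (1140.2 ± 344 against 7.39), Fkbp11 (4.95 ± 0.18), Ckap4 (4.94 ± 0.18) and Trp53inp1 (5.12 ± 0.18). The lowest in this ranking were Batf, Bcl2a1b (-4.00 ± 0.19), Bcl2a1d (-3.86 ± 0.20), Marcksl1 (-3.72 ± 0.18), Cd83 (-3.51 ± 0.24) and Spib (-3.36 ± 0.16). Each of these had the same direction as deposited. Sdc1, which encodes the sort marker CD138, was 13.6 ± 2.2 against 0.0392 (3.81 ± 0.17, deposited 4.44). Cxcr4 rose to 8.43 ± 0.986 from 1.64 ± 0.357 (1.84 ± 0.17, deposited 1.48), and Cd86 was listed at 0 in GC-PB. Cd44 was 16.9 ± 3.43 (0.64, deposited 0.00), with its call at equal totals lost without GC-PB replicate 2 (0.51). Cd69 (1.04, deposited 0.53) lost its call without Fraction 1 replicate 1 (0.82) or GC-PB replicate 1 (0.43). Myc (-2.46), Irf8 (-3.25), Ebf1 (-1.42), S1pr2 (-1.12) and Mef2b (-0.88) fell, and Foxo1 was 0.13 (adjusted p = 0.619, deposited -0.48).

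The secretory machinery rose as a whole. In the plasma cell programme 24 of 25 tested members rose, 25 adjusted over the list alone (camera adjusted p = 7.04e-05 with an estimated correlation). Mzb1 was 238 ± 16.2 against 10.2 ± 0.4. In the unfolded protein response and ER chaperones 34 of 37 tested members rose, 34 adjusted over the list alone (camera adjusted p = 0.00041 with an estimated correlation). Hsp90b1 (4.95), Ssr4 (4.02) and Pdia4 (3.99) were among them. In the interferon response 11 of 22 tested members rose and 2 fell, 12 and 2 adjusted over the list alone (camera adjusted p = 0.0253 with an estimated correlation). Ifi27l2a was 80 ± 9.13 against 9.7 ± 1.42 (2.92), and Bst2 (2.91) and Igtp (2.27) rose as well. As deposited, 10 interferon genes were higher and 5 lower.

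B cell identity, growth and activation genes were lower in GC-PB than in Fraction 1, and for some of them this depended on the reference group. As deposited, MYC targets lay above the mean of all genes by 0.15 against Fraction 3 (adjusted p = 0.425) and by 0.23 against DZ (adjusted p = 0.212). Light zone activation lay above it by 0.23 against DZ (adjusted p = 0.787), and Myc changed by 1.18 against DZ (adjusted p = 0.000413). These references lie across the divide in Xist and the constant, which was 0.358 on average in GC-PB, 0.117 in DZ and 0.123 in Fraction 3. The reference group and the divide cannot be told apart in these values. In germinal centre and B cell identity 2 of 29 tested members rose and 21 fell, 2 and 21 adjusted over the list alone (camera adjusted p = 0.00217 with an estimated correlation). Of the MYC targets 1 of 40 tested members rose and 35 fell, 1 and 37 adjusted over the list alone (camera adjusted p = 0.00434 with an estimated correlation). Npm1, which encodes nucleophosmin, was 13.7 ± 2.08 against 136 (-3.23), and Ncl changed by -2.81. Of the NF-kB and CD40 targets 23 of 29 tested members fell, 23 adjusted over the list alone (camera adjusted p = 0.00796 with an estimated correlation). In glycolysis 14 of 20 tested members fell, 15 adjusted over the list alone (camera adjusted p = 0.00145 with an estimated correlation), with Ldha at -3.13. Of the MHC class II genes 2 of 15 tested members rose and 12 fell, 2 and 12 adjusted over the list alone (camera adjusted p = 0.0391 with an estimated correlation). H2-Aa was 15.9 ± 3.25 against 97.1 ± 7.83, and Ciita, the transactivator of these genes, changed by -2.59. Among dark zone genes outside the cell cycle 2 of 18 tested members rose and 10 fell, 3 and 10 adjusted over the list alone (camera adjusted p = 0.0307 with an estimated correlation). As deposited, MYC targets, glycolysis, MHC class II and dark zone genes had adjusted p = 0.0927, 0.0613, 0.0613 and 0.142 with an estimated correlation. With the preset correlation these lists passed (camera adjusted p = 3.2e-14, 2.9e-05, 3.8e-05 and 0.0067).

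Several lists were called with the preset correlation and lost the call with an estimated correlation. Light zone activation had 2 higher and 21 lower of 29 tested genes, 3 and 21 adjusted over the list alone (camera adjusted p = 7.37e-09, and adjusted p = 0.0528 with an estimated correlation). G1/S and DNA replication had 2 higher and 18 lower of 32 tested genes, 2 and 18 adjusted over the list alone (camera adjusted p = 0.000598, and adjusted p = 0.354 with an estimated correlation). Class switching and somatic hypermutation had 0 higher and 9 lower of 20 tested genes, 1 and 9 adjusted over the list alone (camera adjusted p = 0.0265, and adjusted p = 0.0589 with an estimated correlation). Key regulators had 3 higher and 9 lower of 14 tested genes, 3 and 9 adjusted over the list alone (camera adjusted p = 0.0095, and adjusted p = 0.158 with an estimated correlation). Cholesterol synthesis had 1 higher and 8 lower of 20 tested genes, 1 and 9 adjusted over the list alone (camera adjusted p = 0.0322, and adjusted p = 0.095 with an estimated correlation). Its call was lost without Fraction 1 replicate 2 (-0.39 from the mean of all genes) or GC-PB replicate 2 (-0.36). Immediate early genes had 11 higher and 5 lower of 24 tested genes, 11 and 5 adjusted over the list alone (camera adjusted p = 0.000477, and adjusted p = 0.353 with an estimated correlation). Fos, Fosb and Jun, chosen after their values were seen, changed by 5.11, 4.62 and 3.94. GC-PB replicate 1 stood apart, with Jun at 80.8 against 14 and 18.6 in replicates 2 and 3. Oxidative phosphorylation had 9 higher and 10 lower of 48 tested genes, 9 and 10 adjusted over the list alone, with no call at equal totals (camera adjusted p = 0.309). As deposited it lay below the mean of all genes (adjusted p = 0.037, and adjusted p = 0.667 with an estimated correlation). Mitosis had 3 higher and 9 lower of 35 tested genes, 3 and 9 adjusted over the list alone (camera adjusted p = 0.185).

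By limma, 1573 genes were higher and 2491 lower in GC-PB at equal totals, and 1250 higher and 5130 lower as deposited. Donor genotype and tamoxifen treatment go with the GC-PB group in all its libraries.

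**Figure D3:**
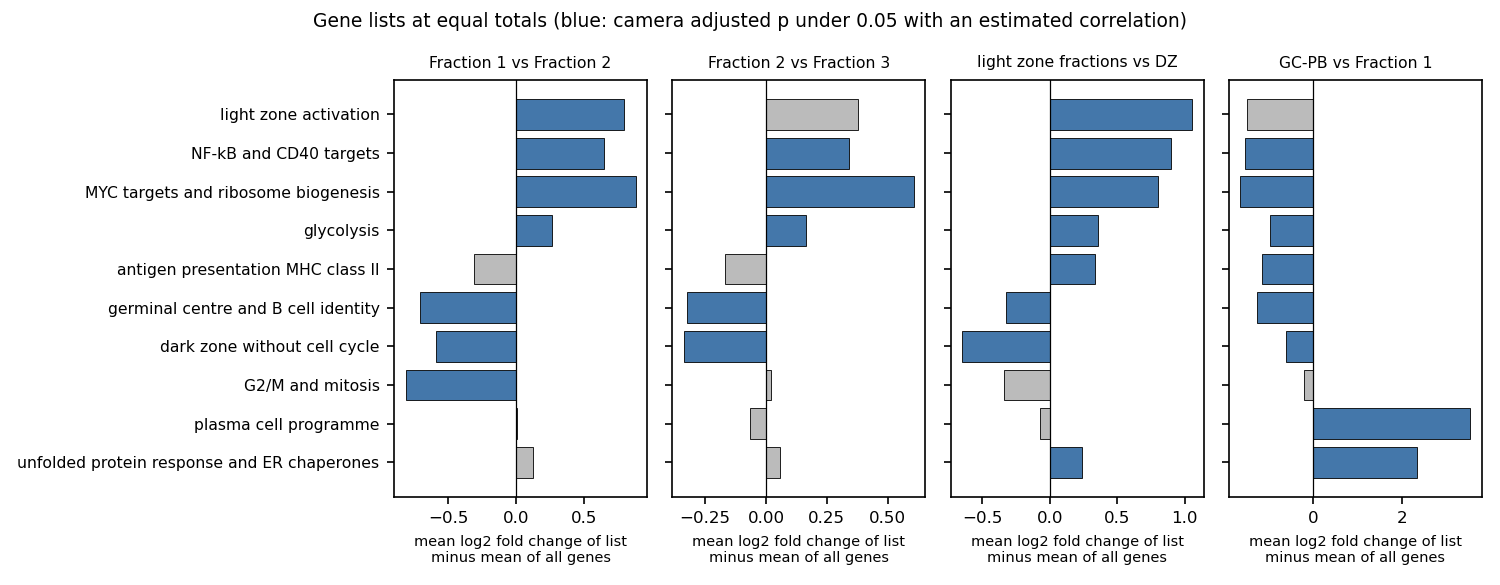
Mean log2 fold change of 10 gene lists minus the mean of all genes, at equal library totals, in 4 comparisons, with a different axis range in each panel. Bars are lists, blue where the camera test with an estimated correlation has an adjusted p under 0.05 and grey where not. The plasma cell programme is blue in GC-PB vs Fraction 1 (adjusted p = 7.04e-05) and grey in Fraction 1 vs Fraction 2 (adjusted p = 0.842). As deposited, in Fraction 1 vs Fraction 2, the germinal centre list has adjusted p = 0.636 and the MHC class II list the opposite direction.

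Genes of the plasmablast transcriptome as a whole, the 200 with the smallest p among those higher in GC-PB than in DZ, were on average slightly higher in Fraction 1 than in Fraction 2. Their mean change at equal totals was 0.09 against -0.05 for all genes, with a median of 0.00 (17 called higher and 10 lower, camera p = 0.00731, and p = 0.0193 with an estimated correlation). As deposited the mean was 1.05 against 0.71 for all genes (147 higher and 1 lower, p = 3.23e-07, and p = 0.0248 with an estimated correlation). GC-PB and DZ lie on opposite sides of the divide in Xist and the constant, as Fraction 1 and Fraction 2 do. Genes that follow the divide therefore enter this programme and count as higher in Fraction 1, so that its change there cannot be assigned to the plasmablast state. Between Fractions 2 and 3 the mean was 0.07 against 0.01 for all genes at equal totals (camera p = 0.0564, and p = 0.0759 with an estimated correlation). As deposited it was 0.29 against 0.19 (p = 8.37e-06, and p = 0.0442 with an estimated correlation). With the genes higher in GC-PB than in Fraction 1 in their place, defined on 1 side of the divide, the mean as deposited differed from that of all genes by -0.09 between Fractions 2 and 3 (camera p = 0.0285 with the preset correlation), and by -0.05 at equal totals (p = 0.124 with the preset correlation). This definition favours genes low in Fraction 1. Of the genes lower in Fraction 1 than in Fraction 2 at equal totals, 74.6% were also lower in Fraction 2 than in Fraction 3. The negative values therefore cannot be assigned to the plasmablast state. The dark zone programme, genes higher in DZ than in Fraction 3, held 53 genes at equal totals and fell in Fraction 1 by 0.39 on average (20 called lower, p = 4.99e-09, and p = 0.000571 with an estimated correlation). As deposited it held 14 genes with a mean of 0.67 against 0.71 for all genes (10 called higher, camera p = 0.423, and p = 0.526 with an estimated correlation). This mean lay below that of all genes while the direction of the camera statistic was up.

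Markers of other cell types were few. Of the 20 T cell genes listed, 4 were tested, with 1 higher (Lck) and 1 lower (Cd2) in the light zone than in DZ at equal totals by limma. Cd2 was 4.14 ± 0.62 in DZ and 2.22, 1.57 and 0.526 in Fractions 3, 2 and 1, and Lck was 1.83 ± 0.479 against 4.36, 5.02 and 3.98. Of the myeloid genes 3 were tested, and Apoe was 25.9 ± 1.69 in DZ, 26.2 ± 0.648 in Fraction 3, 14.1 ± 1.74 in Fraction 2, 3.4 ± 0.559 in Fraction 1 and 22.5 ± 15 in GC-PB. The dendritic cell list had 4 tested genes, the stromal and follicular dendritic cell list 1 (Pecam1) and the NK cell list none. The erythroid list had 2, with Hbb-b2 at 4 ± 2.49 in Fraction 3 and listed at 0 in GC-PB. These lists had too few tested genes for a set test.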

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

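The equal totals, the median ratios, the library weights, Fractions 2 and 3 alone, the programme definitions from GC-PB vs Fraction 1 or without GC-PB replicate 1, and all alternatives run at equal totals were chosen after seeing the data. The cause was not tested for any change given here, except that a test against a fold change of 1.5 asks for larger changes and that leaving out libraries leaves fewer samples. Scaling to the ERCC spike-in, scaling factors and tests for counts, and totals without mitochondrial genes were not run. Depth may limit what low genes can show. In the simulated data depth was not varied, and recovery was lower over all genes than above the naming minimum.

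Counts of genes changed, as deposited. For Fraction 1 vs Fraction 2, 6183 became 1011 at equal totals, 910 by median ratios and 2821 in the test against a fold change. For Fraction 2 vs Fraction 3, 301 became 547 with the stricter filter, 150 with the replicate block, 109 with pseudocount 10, 1269 with library weights, 77 at equal totals, 44 by median ratios, 1017 with the groups compared alone and 1 against a fold change. For the light zone fractions vs DZ, 3379 became 981 at equal totals, 863 by median ratios, 6862, 386 and 27 with Fraction 1, 2 or 3 alone, 127 with Fractions 2 and 3 and 233 against a fold change. For GC-PB vs Fraction 1, 6380 became 4064 at equal totals, 4048 by median ratios, 3505, 4232 and 4069 against Fraction 2, Fraction 3 and DZ, and 3075 against a fold change.

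At equal totals, 1011 genes of Fraction 1 vs Fraction 2 became 1707 with library weights, 1533 with the groups compared alone and 53 against a fold change. The 77 of Fraction 2 vs Fraction 3 became 143 with the stricter filter, 40 with the replicate block, 32 with pseudocount 0.1, 154 with library weights, 189 with the groups compared alone and 1 against a fold change. The light zone count of 981 became 269 with Fractions 2 and 3 and 63 against a fold change, and the GC-PB count of 4064 became 1355 against a fold change.

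With 1 library left out, the counts as deposited ran from 5491 to 6064, 42 to 201, 2125 to 3444 and 5914 to 6115 in the 4 comparisons, and at equal totals from 551 to 683, 17 to 39, 574 to 944 and 3497 to 3827. The ratios of library totals ran from 2.69 to 2.82 (Fraction 1 to 2), 1.26 to 1.35 (2 to 3), 0.901 to 0.977 (3 to DZ) and 0.629 to 0.682 (GC-PB to Fraction 1). The plasmablast programme, as its mean minus that of all genes, ran from 0.319 to 0.351 in Fraction 1 vs Fraction 2 and 0.0817 to 0.115 in Fraction 2 vs Fraction 3 as deposited, and from 0.122 to 0.152 and 0.0428 to 0.0732 at equal totals. The dark zone programme ran from -0.0715 to -0.0168 as deposited and -0.345 to -0.329 at equal totals.

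Defined from GC-PB vs Fraction 1, the plasmablast programme reversed to -0.0852 in Fraction 2 vs Fraction 3 as deposited, with the limit given above for this definition. In Fraction 1 vs Fraction 2 it was -0.247 as deposited and -0.0642 at equal totals, but these values test nothing, since the same Fraction 1 libraries enter definition and test with opposite signs and pull the mean down without any effect. As first defined, it was 0.0596 in Fraction 2 vs Fraction 3 at equal totals and no longer passed, but passed there without Igj (0.0720), with no filter (0.0655), pseudocount 0.1 (0.114), library weights (0.0643), the groups compared alone (0.0754), 50 genes (0.153), without Fraction 2 replicate 2 (0.0732) and with a definition without GC-PB replicate 1 (0.0737), and by median ratios it passed at 0.0704. The dark zone programme passed at -0.339 at equal totals and -0.318 by median ratios.

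Lists reversed are given as mean minus that of all genes, where camera called them in at least 1 of the 2 settings. Lists without a call turned as well at equal totals. In Fraction 1 vs Fraction 2 these included key regulators (0.285 to -0.0951) and memory B cell markers (-0.122 to 0.0646). MHC class II in Fraction 1 vs Fraction 2 turned to -0.0405 with the stricter filter, -0.316 at equal totals and -0.270 by median ratios, and in Fraction 2 vs Fraction 3 to -0.168 and -0.181 on these scales. Against DZ, mitosis was 0.0649 in Fraction 2 alone and oxidative phosphorylation -0.143 in Fraction 3 alone. Oxidative phosphorylation in GC-PB turned to 0.0797 with the stricter filter, 0.0763 with pseudocount 0.1, 0.116 at equal totals, 0.260 by median ratios, and 0.585, 0.907 and 0.764 against Fraction 2, Fraction 3 and DZ. MYC targets in GC-PB were 0.151 against Fraction 3 and 0.230 against DZ, light zone activation 0.232 and cholesterol synthesis 0.00501 against DZ.

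Genes are given as reversed only where limma called them in at least 1 of the 2 settings. Named genes without a call did not all keep their sign either. Reversed at equal totals in Fraction 1 vs Fraction 2 were Cd79b (-0.50), Cdc20 (-0.37), Ccna2 (-0.53), Cenpf (-0.54), Pou2f2 (-0.34), Gna13 (-0.45) and Cd69 (-0.11). So were Cxcr4 (-0.84), Ptprc (-1.13), Xbp1 (-0.26), Bach2 (-0.88), Foxo1 (-0.85), Irf8 (-0.49) and Spib (-0.51). In the light zone they were Ptprc (-0.14) and Cd44 (-0.069), and in GC-PB Cd44 (0.64) and Foxo1 (0.13). In the light zone, Spib was 0.50 in Fraction 1 alone, Cd44 -0.27 in Fraction 2 alone, Odc1 -0.0027, Cd44 -0.67 and Ebf1 -0.023 in Fraction 3 alone, Cd44 -0.47 in Fractions 2 and 3, and Bcl6 0.022 in Fractions 2 and 3 at equal totals. In GC-PB, Cd44 was 2.92 against Fraction 2. Against Fraction 3, Pa2g4 was 0.20, Ncl 0.23, Cd44 3.32, Myc 0.051 and Foxo1 0.066, and against DZ, Batf was 0.41, Pa2g4 0.25, Ncl 0.10, Pgam1 0.028, Cd44 2.65 and Myc 1.18. Between the deposited scale and equal totals, 145 gene results and 73 list results stayed called in the same direction or stayed without a call. Those without a call count among them also where their direction turned. With 1 library left out as deposited, these numbers were 1401 and 661, and 53 and 26 results lost their call.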

Other observations

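The tests of sex, of the genes between Fractions 1 and 2, and of the library total were chosen after their results were seen, as were the splits at equal totals and those that keep the light zone fractions apart or leave out Fraction 1. The other splits were planned.

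The means of Ccnd2 and Batf were higher at each step from DZ through Fraction 3 and Fraction 2 to Fraction 1. Ccnd2 was 0.0152 in DZ, 0.293 in Fraction 3, 5.38 in Fraction 2 and 30.7 in Fraction 1 (mean of 3 libraries at equal totals), and Batf was 0.249, 0.848, 4.39 and 20.9. Cxcr4 ran the other way, from 11.8 through 6.5 and 3.78 to 1.64. Fraction 3 was closest to DZ, with 64 genes higher and 54 lower than DZ at equal totals (13 and 14 as deposited), against 186 and 206 for Fraction 2 (339 and 47) and 1084 and 1277 for Fraction 1 (6729 and 133). Of these comparisons with DZ, only that of Fraction 1 crosses the divide in Xist and the constant. The step to Fraction 1 therefore cannot be assigned to cell state alone. Ccnd2 stayed high in GC-PB (28.1 ± 5.44), where Batf was 0.359.

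Migration genes split in GC-PB, with 6 higher and 6 lower of 19 tested genes, 6 and 6 adjusted over the list alone, and no call as a list (camera adjusted p = 0.4). The members named here were chosen after their values were seen. Itga4 (2.56), an integrin chain, Klf2 (2.44), a regulator of egress, and Cxcr3 (1.28) rose, and as deposited they changed by 2.62, 2.40 and 1.53. Cxcr5, the receptor for the follicle chemokine, fell (-2.06, deposited -3.09). The GC-PB libraries differed in immediate early genes, with Fos at 168, 72.1 and 95, Egr1 at 39.1, 14.8 and 13.6, and Klf6 at 47, 7.49 and 14.3 in replicates 1, 2 and 3. Without GC-PB replicate 1, 3703 genes were called in GC-PB vs Fraction 1 at equal totals and 5914 as deposited.

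Xist and Y-linked transcripts divided the libraries by group. In 15 of 15 libraries either Xist or the summed Y-linked transcripts, but not both, were above 1, which is consistent with cells from mice of different sex. In 0 libraries were both above 1, which argues against male and female cells mixed within libraries. Summed Y-linked transcripts in Fraction 1 were 0.00298 times those in Fraction 2, which argues against Xist regulated by cell state alone. The labels give no sex, and whether the mice differed in sex by group stays a hypothesis.

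Genes that differ between Fractions 1 and 2 could stem from the cell state or from whatever else divides these libraries. A preparation batch as the whole cause is argued against, since 81.1% of the 424 genes higher in Fraction 1 at equal totals were also higher in Fraction 2 than in Fraction 3, 2 groups on the same side of the divide, and 74.6% of the 587 lower genes were also lower. Between Fraction 3 and DZ, also on 1 side, 53.8% of the higher and 43.1% of the lower genes had the same direction, so that the overlap did not reach that step. Between Fractions 2 and 3, 50% of all genes were higher. Simulations in which Fraction 2 was shared by both comparisons without an effect gave 10.8%. They held no batch effect in Fraction 1, so that 10.8% is not the share that a batch would give. Genes of the sex chromosomes made up 3.78% of the called genes with a known position, against 3.28% of the tested genes, so they are not the whole cause. The share due to cell state cannot be told apart from the divide, since 0 groups had libraries on both sides of it.

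The ratio of molecules between Fraction 1 and Fraction 2 was 0.996, while that of the constant was 2.77. With the constant read as 1 molecule, the higher library total of Fraction 1 was not one of molecules counted. A larger constant therefore accounts for it in the table, and what the constant stands for is not stated. More mRNA per cell in Fraction 1 is a candidate explanation that stays open, because the table holds no ERCC rows, and GC-PB, on the same side of the divide, had a constant 1.12 times that of Fraction 1.

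With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The groups compared alone gave 6018 genes in Fraction 1 vs Fraction 2 (1 of 10 splits gave as many, highest other 0), 1017 in Fraction 2 vs Fraction 3 (1 of 10, highest other 0) and 4956 in GC-PB vs Fraction 1 (1 of 10, highest other 0), and at equal totals 1533, 189 and 3717 (1 of 10 each, highest other 0). The plasmablast programme differed from all genes by 0.448 in Fraction 1 vs Fraction 2 (1 of 10, highest other 0.199) and 0.131 in Fraction 2 vs Fraction 3 (1 of 10, highest other 0.0783), and the dark zone programme by 0.0568 in size (2 of 10, highest other 0.0823). For the light zone against DZ, with the 9 light zone libraries pooled, the real split called 1 gene, and 4 of 100 splits called as many (highest other 1). The split of the Fraction 1 libraries from the other 9 called 7774 genes (2437 at equal totals), which points to the structure of these samples. With the light zone fractions kept apart in the fit, the real split called 4096 genes as deposited (1 of 100, highest other 0) and 1265 at equal totals (1 of 100, highest other 101, in a split that kept the DZ libraries together). Most other splits mix Fraction 1 libraries into other groups, which raises the spread. These low shares therefore reflect how far Fraction 1 stands apart, by cell state or by the divide, and do not test DZ. Among the 9 libraries of DZ and Fractions 2 and 3, on 1 side of the divide, the real assignment called 341 genes between Fractions 2 and 3 and DZ as deposited (4 of 100, highest other 1311) and 373 at equal totals (1 of 100, highest other 262). In both highest others Fraction 2 stood in the place of DZ, which points to the structure of these samples. Few random assignments of the 9 libraries called as many genes, but this is not specific to DZ. The libraries of a group may be technical replicates, so that these shares do not speak on chance differences between animals.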
